A study of Arabidopsis thaliana with 18 samples.

How the data were processed

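Seeds of Arabidopsis thaliana with an intact (+WT) or a DS-deleted (ΔDS) complementing gene were profiled by RNA-seq in 3 conditions, with 3 replicates per group and 18 samples. Per the series' design text, libraries were read from both ends. Strandedness, the read counter and the annotation version are not given in the sources used here. HISAT2 and DESeq2 are named in the submitters' processing notes, without versions, and TAIR10 is given there as the genome build.

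The files used were 3 tables of the authors' comparisons, 1 per condition, each with 33602 genes and no values per library. Per the file headers they hold the usual DESeq2 result columns. The mean over libraries of normalised coverage is the signal column deposited by the authors, made of read counts divided by size factors. The log2 fold change and its standard error are deposited by the authors on the log2 scale and are not shrunk. The Wald statistic is a score deposited by the authors and equals the fold change over its error. The p-value and the Benjamini-Hochberg adjusted p-value are those deposited by the authors, and an adjusted value is missing where the authors' DESeq2 run filtered the gene. All 279 organelle genes were listed at 0.

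The direction of the fold change is not stated in the headers. It was read as ΔDS over +WT from the order of the names, and if the order were the reverse every sign here would turn.

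The test planned before the data were examined was a count model where counts were given, and the authors' deposited adjusted p, at 0.05, where no value per sample was. The second applied. Group means called implied were computed from the deposited mean and fold change, assuming 3 libraries on each side, and are approximate. The difference of the genotype effect between conditions was tested with an approximate z test of the difference of the deposited log2 fold changes, with the SE from both errors and Benjamini-Hochberg adjustment over genes with an adjusted p in both tables.

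The 18 gene lists, with 284 entries, were written before the data were examined, and 1 entry was dropped because the reference names that locus differently. Lists were compared with all other tested genes by the limma 3.58.1 function cameraPR in R 4.3.3 on the deposited Wald statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 16, 18 and 17 lists with at least 3 tested members in dry, imbibed and salt seeds. The 3 lists added later, each with and without the members seen first, were adjusted apart from these, over 6 tests in each comparison. A correlation could not be estimated without values per library, so a preset of 0.05 and a rank version were run in its place. The median and the test differed in sign for the ABA, oil breakdown and cell wall lists in dry seeds and for the salt list in salt seeds, none of which was called. Named genes were FLOE1, FLOE2 and FLOE3, the 8 largest increases and 8 largest decreases past the threshold whose higher group had at least 20 normalised counts, up to 2 members of each list with the smallest adjusted p, and the 6 largest differences each way between conditions, with the text giving a part of these. A few values of genes named for one condition are repeated for another. Of the 33602 identifiers 32835 matched a locus of the TAIR10.1 reference, which served for names, products, exon lengths and neighbours.

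Alternatives were the adjustment over all genes with a p, a mean of at least 5 CPM, a fold change of at least 2, scaling by library totals as implied by the tables, centring on the median gene, removal of a lowess trend (span 0.3) over exon length, and a t distribution with 4 degrees of freedom (8 for differences between conditions). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used. The steps were tested on simulated data with the real errors and 200 changed genes. Noise was drawn with the same errors that the test uses, so this does not show whether those errors are right. For a log2 change of 1, 94.5% were recovered in dry (16597 genes), 86.0% in imbibed (19430 genes) and 93.0% in salt seeds (18518 genes), and for a change of 0.5, 71.5%, 38.5% and 62.0%. For the difference between salt and imbibed seeds (18219 genes) 80.0% were recovered at 1 and 19.0% at 0.5, and between imbibed and dry seeds (16228 genes) 82.5% and 17.0%. The list test called 2.5% of 1000 random lists of 20 genes on the imbibed statistic. Such lists hold unrelated genes, so the share does not carry over to lists of genes that vary together.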

Results

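RNA was sequenced from Arabidopsis thaliana seeds of 2 complemented genotypes, one carrying an intact copy of the gene under study (+WT) and the other a copy with the DS segment deleted (ΔDS). From knowledge of the study, the gene is FLOE1 (AT4G28300), whose protein condenses in the embryo as the seed takes up water. Each genotype was sampled as dry seeds, as imbibed seeds and as seeds imbibed with salt, with 3 replicates in each of the 6 groups and 18 samples in all. Imbibed seeds spent 5 days at 4 °C in darkness on medium and then 4 hours in light at 22 °C, and the salt group had the same treatment with 220 mM NaCl. The labels do not say whether replicates came from separate mother plants, nor whether each genotype is a single transgenic line. The p-values thus measure the spread between these samples only. Effects of the deletion cannot be separated from those of a line, an insertion or the amount of FLOE1 transcript.

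Values are those of the authors' comparison of ΔDS with +WT seeds in each condition, as log2 fold changes with standard errors (SE). The column headers do not state the direction, and a positive value was read as higher in ΔDS, after the order of the genotypes in the titles. Mean normalised counts summed to 26367661 in the dry, 24526188 in the imbibed and 26080227 in the salt table of the authors. Library totals are not given. The value of 1 read, seen in genes with a single read, gave 6 libraries per table whose size factors spanned 1.36-fold in dry, 1.54-fold in imbibed and 1.38-fold in salt seeds. Size factors averaged 1.14, 1.12 and 1.20 times higher in the ΔDS libraries in that order. The 10 most abundant genes held 16.9%, 13.4% and 18.1% of the normalised counts.

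Counts of FLOE1 itself were far lower in ΔDS than in +WT seeds in every condition. In the authors' deposited table for dry seeds its transcript was 46.1-fold lower (log2 fold change -5.53 ± 0.090, SE), with implied means of 8288 normalised counts in +WT and 179.7 in ΔDS. The authors' deposited table gave a 47.8-fold lower level in imbibed seeds (-5.58 ± 0.16) and 31.9-fold in salt (-5.00 ± 0.067). How reads of the deleted copy were counted is not given in the sources used here. These values alone thus do not show whether transcript level or counting differed. If the level differed, effects of the deletion cannot be separated from those of less FLOE1 transcript. AT4G28290, the gene next to FLOE1, shares 0 words of 31 bases with it. That gene was lower too, at -5.54 in dry, -2.17 in imbibed and -7.17 in salt seeds by the authors' comparisons. AT4G28290 lies within the bounds of LLG3 (AT4G28280), which is on the other strand. Strandedness and the handling of reads in that overlap are not given, so its counts may not be separate from those of LLG3. FLOE1 is a protein-coding gene on chromosome 4, from 14014646 to 14017097 on the plus strand in TAIR10.1, with 2359 bases of exon. Its relative AT5G14540 (FLOE2) did not pass the test in any authors' deposited table (log2 fold changes of -0.01, 0.25 and 0.17 in dry, imbibed and salt seeds). Adjusted over the list alone 1 family member rose in imbibed seeds, and scaled by library totals 1 rose in imbibed and 1 in salt seeds. The other relative, AT3G01560 (FLOE3), fell in imbibed seeds by the authors' deposited table (-0.58 ± 0.15, adjusted p = 7.30e-04) and had values of -0.09 in dry and -0.11 in salt seeds.

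**Figure D1:**
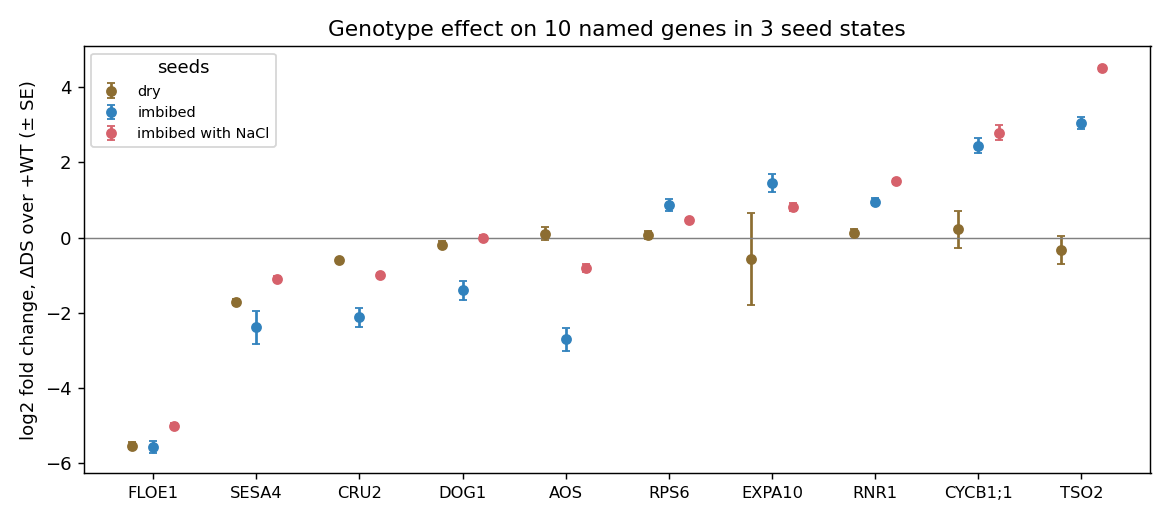
Log2 fold change of ΔDS over +WT seeds (y axis) for 10 named genes (x axis) in dry, imbibed and salt-imbibed seeds, from the authors' deposited tables. Points are the deposited fold changes and bars their SE. FLOE1 lies between -5.58 and -5.00 in the 3 conditions, and TSO2 goes from -0.32 in dry to 4.50 in salt seeds.

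The dry comparison asks how the genotypes differ before water uptake. Dry ΔDS seeds had lower transcripts of seed storage and late embryogenesis abundant (LEA) proteins and higher transcripts of some small heat shock proteins. Of 17 storage and oil body genes tested, 11 fell and none rose (14 fell adjusted over the list alone), with a median log2 fold change of -0.22. The authors' deposited table put the 2S albumin gene SESA4 (AT4G27170) 3.27-fold lower in ΔDS (-1.71 ± 0.070), SESA5 (AT5G54740) at -0.76 ± 0.055, SESA3 (AT4G27160) at -0.70 ± 0.058 and the cruciferin gene CRU2 (AT1G03880) at -0.60 ± 0.043. Albumin genes are similar copies, and how reads were shared among them is not given in the sources used here. Among LEA genes, which encode protective proteins of the dry seed, 17 of 24 fell and none rose (19 fell adjusted over the list alone, and 8 scaled by library totals), with a median of -0.21. The authors' deposited table gave -0.49 ± 0.067 for EM1 (AT3G51810) and -0.31 ± 0.043 for AT3G53040.

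Of 17 heat shock and chaperone genes tested in dry seeds, 7 rose and none fell (8 rose and 2 fell adjusted over the list alone). In the authors' deposited table the small heat shock genes HSP17.6II (AT5G12020) and ATHSP22.0 (AT4G10250) were 0.57 ± 0.063 and 0.53 ± 0.067. Ribosomal protein genes rose in 1 of 26 cases (4 scaled by library totals), SAG24 (AT1G66580), at 0.43 ± 0.058 in the authors' deposited table. In the abscisic acid (ABA) and dormancy list 2 of 21 fell (2 adjusted over the list alone), namely ABI5 (AT2G36270, -0.17 ± 0.041) and E12A11 (AT1G18100, also called MFT, -0.24 ± 0.077) in the authors' deposited table, and neither passed when scaled by library totals. No member of the gibberellin (12 tested), cell wall loosening (8), cell cycle (7) or defence and wounding (2) lists passed the test, also when adjusted over the list alone. Few members passed in the other lists, with 1 higher and 1 lower of 15 salt and osmotic genes (1 and 2 adjusted over the list alone), 1 lower of 12 photosynthesis genes (1), 1 lower of 15 oil breakdown genes (1), 1 higher of 6 light signalling genes (2), 1 higher of 7 embryo and meristem markers (1), 1 higher of 5 seed coat markers (1 higher and 1 lower) and 1 each way of 2 endosperm markers (1 and 1). Scaled by library totals, 3 light signalling, 2 oil breakdown and 2 salt and osmotic genes were higher. With the length trend removed, 0 light signalling genes, embryo and meristem markers or seed coat markers were higher, and 3 oil breakdown genes were lower. At an unadjusted p under 0.05 the whole table held 2812 genes.

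Single genes moved far more than these groups. By the authors' deposited table NHL22 (AT4G09590), a member of the NDR1/HIN1-like family, was 87.4-fold higher in dry ΔDS seeds (6.45 ± 0.41), from an implied 4.94 to 432 normalised counts. Other large increases in the authors' deposited table included AT3G46710 (6.72 ± 1.32), near 0 in +WT, the glycosyltransferase gene AT3G46700 (4.46 ± 0.99) and AT5G13210 (4.38 ± 0.38). Among genes with at least 20 implied normalised counts in the higher group, the largest decreases after FLOE1 in the authors' deposited table were VGDH1 (AT2G47030, -2.36 ± 0.56), AT2G13547 (-2.21 ± 0.45), ACA3 (AT5G04180, -2.15 ± 0.67), AGP23 (AT3G57690, -1.76 ± 0.58), BGAL11 (AT4G35010, -1.76 ± 0.57), SESA4 and the ferritin gene FER1 (AT5G01600, -1.57 ± 0.11). Among antioxidant genes, 3 rose and 2 fell of 12 tested (4 and 2 adjusted over the list alone), with GSTU19 (AT1G78380) at 0.53 ± 0.048 and the catalase CAT3 (AT1G20620) at -0.29 ± 0.042 in the authors' deposited table.

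In all, 1005 of 16597 genes tested passed an adjusted p of 0.05 in dry seeds (491 higher and 514 lower in ΔDS), with a median 1.27-fold change. By limma's competitive list test with a preset correlation of 0.01, the storage (adjusted p = 2.79e-61), LEA (2.64e-21), heat shock (2.34e-09) and ribosome (0.00977) lists stood apart from other genes. The ribosome call was lost at a preset correlation of 0.05 (adjusted p = 0.0870). By the rank version of this test the adjusted p was 1.66e-08 for storage, 6.20e-10 for LEA, 3.19e-04 for heat shock and 0.00221 for ribosome. Scaling by library totals put 82.9% of calls higher in ΔDS, against 48.9% as deposited. Fold changes in this table rose with transcript length, from a median of -0.05 in the shortest to 0.07 in the longest of 4 length classes (Spearman's rho 0.277 across 12770 genes, which are not independent replicates).

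The imbibed comparison asks how the genotypes differ once seeds have taken up water and seen light. Imbibed ΔDS seeds had lower storage, LEA, heat shock and ABA-related transcripts, and higher transcripts for cell wall loosening, ribosomes and the cell cycle. All 17 storage and oil body genes fell (17 adjusted over the list alone), with a median of -1.27. The authors' deposited table put SESA5 6.63-fold lower (-2.73 ± 0.55), CRU2 4.35-fold lower (-2.12 ± 0.26) and SESA3 at -1.54 ± 0.28. Of 23 LEA genes 19 fell (20 adjusted over the list alone), with AT4G36600 at -1.69 ± 0.27 and AT3G22490 at -1.84 ± 0.33 in the authors' deposited table. Heat shock and chaperone genes fell in 12 of 19 cases and rose in 1 (13 and 1 adjusted over the list alone), among them AT2G29500 (-1.78 ± 0.29) and the seed heat shock factor HSFA9 (AT5G54070, -1.88 ± 0.34) in the authors' deposited table.

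Of 21 ABA and dormancy genes 11 fell and 1 rose (12 and 1 adjusted over the list alone, and 7 and 2 scaled by library totals). DOG1 (AT5G45830), a main dormancy gene, was 2.63-fold lower (-1.40 ± 0.26, adjusted p = 1.49e-06) and the phosphatase gene AHG1 (AT5G51760) stood at -1.33 ± 0.27 in the authors' deposited table. PIL5 (AT2G20180), the light-labile repressor of germination also called PIF1, was at -0.87 ± 0.15 in the authors' deposited table. AOS (AT5G42650), which makes the precursor of jasmonate, fell 6.52-fold in the authors' deposited table (-2.70 ± 0.31).

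Cell wall loosening genes rose in 16 of 17 cases and none fell (16 adjusted over the list alone), with a median of 1.57. In the authors' deposited table the xyloglucan-modifying genes XTH31 (AT3G44990) and XTH16 (AT3G23730) were 5.69-fold (2.51 ± 0.30) and 4.50-fold (2.17 ± 0.28) higher. Of 26 ribosomal protein genes 25 rose (26 adjusted over the list alone), with a median of 0.66 and RPL23AA (AT2G39460) at 0.95 ± 0.15 in the authors' deposited table. Cell cycle genes rose in 10 of 12 cases (10 adjusted over the list alone), led by the ribonucleotide reductase subunit TSO2 (AT3G27060, 3.05 ± 0.16) and the cyclin CYCB1;1 (AT4G37490, 2.45 ± 0.19) in the authors' deposited table. Of 8 embryo and meristem markers 5 rose and none fell (5 adjusted over the list alone, and 8 scaled by library totals), including SHR (AT4G37650, 1.83 ± 0.28) and the epidermal gene PDF1 (AT2G42840, 2.04 ± 0.31) in the authors' deposited table.

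Other lists were mixed. Gibberellin genes rose in 5 and fell in 3 of 18 cases (6 and 3 adjusted over the list alone, and 8 and 2 scaled by library totals), with the gibberellin-regulated GASA6 (AT1G74670) at 1.81 ± 0.27 and AT5G14920 at 1.42 ± 0.24 in the authors' deposited table. The salt and osmotic list had 7 higher and 9 lower of 21 (7 and 9 adjusted over the list alone, and 7 and 6 scaled by library totals), from COR47 (AT1G20440, 2.35 ± 0.25) and KIN2 (AT5G15970, 2.97 ± 0.38) to ADH1 (AT1G77120, -1.15 ± 0.19) in the authors' deposited table. Photosynthesis genes rose in 3 and fell in 2 of 20 cases (3 and 1 adjusted over the list alone), and oil breakdown genes rose in 4 and fell in 3 of 16 (4 and 3 adjusted over the list alone, and 10 and 1 scaled by library totals). Light signalling genes rose in 4 and fell in 2 of 9 cases (4 and 2 adjusted over the list alone), and 1 of 3 defence genes fell (1). Antioxidant genes rose in 2 and fell in 7 of 13 cases (2 and 7 adjusted over the list alone, and 2 and 4 scaled by library totals), and their list did not pass (limma, adjusted p = 0.0706). Endosperm markers split, since EPR1 (AT2G27380), the most abundant member, was at -1.14 ± 0.24 and AGL62 (AT5G60440) at 6.02 ± 1.31 in the authors' deposited table. Of 6 seed coat markers 3 rose (4 rose and 2 fell adjusted over the list alone), with TTG2 (AT2G37260) at 2.06 ± 0.43 in the authors' deposited table.

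In imbibed seeds 7924 of 19430 genes tested passed (4130 higher and 3794 lower), with a median 1.58-fold change and 2159 changed at least 2-fold. A t distribution with 4 degrees of freedom for the deposited statistics left 0 calls here, 1 in dry and 3 in salt seeds. FLOE1, 47.8-fold lower in imbibed seeds, was thus not called either. A reference this wide can hardly pass any gene and does not grade single calls. The list test called 9 lists, with adjusted p = 2.93e-10 for storage, 1.11e-08 for LEA, 2.86e-04 for heat shock, 9.31e-04 for ABA, 6.48e-14 for cell wall loosening, 6.48e-14 for ribosome, 5.55e-14 for cell cycle and 8.40e-04 for embryo and meristem (limma, preset correlation 0.01). The ninth, the FLOE family, rests on FLOE1. With library totals as scaling, which moves the median gene by 0.19, 77.2% of calls were higher against 52.1% as deposited. The median SE of genes with 500 to 2000 mean normalised counts was 0.129 in this table, against 0.0860 in dry and 0.0878 in salt seeds.

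**Figure D2:**
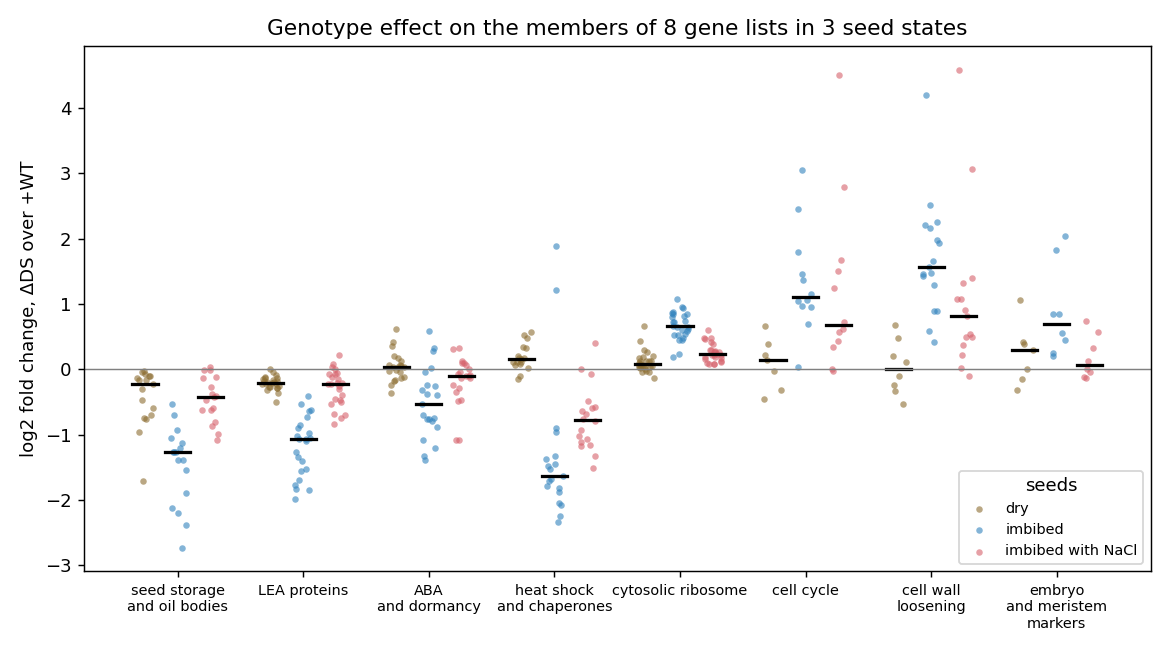
Log2 fold change of ΔDS over +WT seeds (y axis) for tested members of 8 gene lists (x axis) in dry, imbibed and salt-imbibed seeds, from the authors' deposited tables. Each point is a gene and each black line a list median, such as 1.57 for cell wall loosening and -1.27 for storage genes in imbibed seeds.

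The salt comparison asks how the genotypes differ when 220 mM NaCl is present during imbibition, a treatment that holds back germination. ΔDS seeds in salt again had lower storage, LEA and heat shock transcripts. Transcripts of most ribosome genes and of some cell wall loosening and cell cycle genes were higher. Storage and oil body genes fell in 12 of 17 cases and LEA genes in 16 of 24, none rose in either list (12 and 17 fell adjusted over the list alone), and the medians were -0.42 and -0.23. The authors' deposited table gave -1.09 ± 0.061 for SESA4, -0.86 ± 0.051 for SESA5, -0.84 ± 0.063 for EM1 and -0.75 ± 0.055 for AT4G36600. Heat shock and chaperone genes fell in 10 of 18 cases (11 adjusted over the list alone), with HSP17.4 (AT3G46230) at -1.07 ± 0.077 and HSP17.6A (AT5G12030) at -1.18 ± 0.15 in the authors' deposited table. With library totals as scaling 3 LEA genes rose and 10 fell.

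Ribosomal protein genes rose in 21 of 26 cases (22 adjusted over the list alone) by a median of 0.23, with RPS6 (AT4G31700) at 0.47 ± 0.053 in the authors' deposited table. Of 15 cell wall loosening genes 7 rose (10 adjusted over the list alone), including the expansins EXPA10 (AT1G26770, 0.81 ± 0.10) and EXPA8 (AT2G40610, 1.07 ± 0.21) in the authors' deposited table. Cell cycle genes rose in 5 of 12 cases (5 adjusted over the list alone). The authors' deposited table put TSO2 22.6-fold higher (4.50 ± 0.070), from an implied 506 to 11446 normalised counts, the large ribonucleotide reductase subunit RNR1 (AT2G21790) at 1.50 ± 0.064 and CYCB1;1 at 2.78 ± 0.20.

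ABA and dormancy genes fell in 5 of 21 cases (5 fell and 1 rose adjusted over the list alone), among them the ABA synthesis gene ABA1 (AT5G67030, -0.29 ± 0.051) and the kinase gene SNRK2.3 (AT5G66880, -0.35 ± 0.063) in the authors' deposited table. Scaled by library totals, 6 of them rose and 2 fell. DOG1 was at 0.00 ± 0.061 in salt in the authors' deposited table and did not pass. The gibberellin synthesis gene GA20OX3 (AT5G07200) was the 1 gibberellin gene of 19 to pass, at 0.40 ± 0.079 in the authors' deposited table, while 5 were higher when scaled by library totals. In the salt and osmotic list 2 rose and 3 fell of 19 (2 and 3 adjusted over the list alone, and 4 and 2 scaled by library totals), with GolS1 (AT2G47180) at -0.59 ± 0.069 and LTI78 (AT5G52310) at 0.51 ± 0.071 in the authors' deposited table. Antioxidant genes rose in 2 and fell in 5 of 12 cases (2 and 6 adjusted over the list alone, 3 and 2 scaled by library totals), with CAT3 at -0.46 ± 0.054 in the authors' deposited table.

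Oil breakdown genes rose in 1 and fell in 4 of 16 cases (2 and 5 adjusted over the list alone), light signalling genes in 1 and 1 of 9 (3 and 1) and endosperm markers in 1 and 1 of 3 (2 and 1). Library totals as scaling turned these to 9 higher and 2 lower oil breakdown genes and 5 higher and 0 lower light signalling genes. Of 17 photosynthesis genes 1 fell (1 adjusted over the list alone), both defence genes tested fell (2), 1 of 7 seed coat markers rose (1), and no embryo or meristem marker of 8 passed. Scaled by library totals, 2 photosynthesis genes rose and 0 fell, 1 defence gene fell, and 2 seed coat and 2 endosperm markers rose.

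The largest increases in salt in the authors' deposited table included the ATPase gene AT2G18193 (7.71 ± 0.94), with an implied 4.85 normalised counts in +WT and 1019 in ΔDS, and NHL22 (6.68 ± 0.62). With the same minimum of 20, the largest decreases in the authors' deposited table were AT4G28290 (-7.17 ± 1.32), the gene next to FLOE1, then FLOE1, the low-oxygen regulator AT3G10040 (-2.36 ± 0.65), AT1G51340 (-2.31 ± 0.69), AT3G39230 (-2.22 ± 0.56) and the neighbouring wound-responsive genes AT4G10270 (-2.12 ± 0.43) and AT4G10265 (-2.09 ± 0.65). Altogether 2586 of 18518 genes passed (1292 higher and 1294 lower), with a median 1.29-fold change. Among those changed at least 2-fold, 283 were higher and 66 lower. The list test called 8 lists, among them storage (adjusted p = 1.24e-42), LEA (6.73e-22), heat shock (4.10e-11), ribosome (1.58e-17), cell cycle (3.62e-44), cell wall loosening (1.60e-05) and antioxidant genes (0.0114) by limma with a preset correlation of 0.01. By ranks the adjusted p was 1.67e-06 for storage, 1.12e-06 for LEA and 6.04e-06 for heat shock. It was 1.06e-11 for ribosome and 7.75e-05 for cell wall loosening in the same version. By ranks the antioxidant call was lost (adjusted p = 0.0584), and the cell cycle list had an adjusted p of 0.00129. The smaller cell cycle value leans on TSO2, RNR1 and CYCB1;1, since 7 of its 12 members did not pass. With library totals as scaling, which moves the median gene by 0.16, 89.8% of calls were higher against 1292 of 2586 as deposited.

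The difference between salt and imbibed seeds shows where the genotype effect itself depended on salt. Storage, LEA, ABA and heat shock genes were less reduced in ΔDS with salt than without, and cell wall loosening, ribosome and embryo marker genes less raised. The list tests gave adjusted p = 4.77e-10 for storage, 2.97e-09 for LEA, 0.00136 for ABA, 0.0399 for heat shock, 4.76e-06 for cell wall loosening, 2.71e-14 for ribosome and 0.00136 for embryo and meristem genes (limma, preset correlation 0.01), and the heat shock call was lost at a preset of 0.05 (adjusted p = 0.131). From the authors' deposited tables the difference of log2 fold changes was 1.40 ± 0.26 for DOG1 (adjusted p = 4.69e-05), 1.89 ± 0.33 for AOS and 1.13 ± 0.26 for CRU2. The authors' deposited tables gave -1.80 ± 0.32 for GASA6 (adjusted p = 1.17e-05) and -1.92 ± 0.37 for PDF1. TSO2 went the other way and was raised more with salt, by 1.45 ± 0.17 from the authors' deposited tables (adjusted p = 4.37e-13). Among the most negative differences was the chaperone gene BIP3 (AT1G09080), at 2.68 ± 0.46 in imbibed and -1.47 ± 0.49 in salt seeds of the authors' deposited tables. The most positive included PUP4 (AT1G30840, 2.75 ± 0.80), DIN2 (AT3G60140, 2.51 ± 0.50) and CYP78A6 (AT2G46660, 2.21 ± 0.40) from the authors' deposited tables. The approximate z test of the difference called 1669 of 18219 genes, 1066 more positive and 603 more negative in salt, and a t distribution with 8 degrees of freedom left 0 of them.

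Between imbibed and dry seeds the genotype effect differed for more genes. The dehydrin gene ERD14 (AT1G76180) was -0.54 ± 0.41 in dry and 3.20 ± 0.31 in imbibed seeds of the authors' deposited tables, a difference with an adjusted p of 1.83e-10. FER1, lower in dry ΔDS seeds, was higher in imbibed ones (0.87 ± 0.30) by the authors' deposited table, and the difference passed (adjusted p = 2.38e-11). GSTU19 turned from higher to lower (-0.36 ± 0.10 in imbibed seeds of the authors' deposited table), with an adjusted p of 1.08e-11 for the difference. The heat shock list moved from raised to lowered, with a median of 0.16 in dry and -1.63 in imbibed seeds (adjusted p = 3.34e-07 for the list, limma). The z test called 4062 of 16228 genes, 1377 more positive and 2685 more negative in imbibed seeds, and the t distribution left 127. Under scaling by library totals 52.9% of these were more positive, against 33.9% as deposited.

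Most overlaps between conditions were in the same direction, except for genes raised in dry seeds when compared with imbibed seeds. Of genes tested in both, 944 were higher in ΔDS in imbibed and in salt seeds, against 269 for independent lists, and 1094 were lower in both, against 269. Dry and salt seeds shared 135 higher genes against 33.8 and 227 lower genes against 39.6, and the tables share no libraries. Dry and imbibed seeds shared 314 lower genes against 115 for independent lists, while 118 genes were higher in both against 91.6 and 155 were higher in dry and lower in imbibed seeds against 111. The correlation of fold changes across genes, which are not independent replicates, was 0.532 for imbibed and salt, 0.355 for dry and salt and 0.205 for dry and imbibed seeds. Changes between conditions within a genotype were not tested, because the tables were normalised separately.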

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

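The DNA damage and jasmonate lists were chosen only after the fold changes had been seen, as were the tests of expression level, transcript length, scaling, random positions and reads shared between similar copies. Results stand here because the genotype effect differed between conditions in the approximate z test of the authors' deposited log2 fold changes, or in the list test on that z. List medians are over the members tested in each table, such as 8 in dry and 17 in imbibed seeds for cell wall loosening, 7 and 12 for cell cycle and 18 and 25 for DNA damage, so their differences are not shifts of the same genes. The list test of imbibed minus dry seeds used the 8, 7 and 18 tested in both. With a t distribution of 8 degrees of freedom in place of the z, 0 genes differed in salt minus imbibed and 127 in imbibed minus dry seeds.

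Seed reserve and protection genes were reduced most in imbibed seeds. From the authors' deposited tables, the log2 effect in imbibed minus dry seeds was -1.52 for CRU2, -0.84 for SESA3, -1.97 for SESA5, -1.49 for EM1, -1.62 for AT3G22490 and -1.41 for AT4G36600. In salt minus imbibed seeds of the authors' deposited tables it was 1.13 for CRU2, 0.94 for SESA3, 1.30 for SESA4, 1.87 for SESA5, 1.13 for AT3G22490 and 0.94 for AT4G36600. The list medians differed by -1.05 (storage) and -0.86 (LEA) in imbibed minus dry seeds, and by 0.85 and 0.84 in salt minus imbibed seeds.

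ABA and dormancy genes followed. In imbibed minus dry seeds of the authors' deposited tables the difference was -0.57 for ABI5, -1.21 for DOG1, -1.21 for AHG1, -1.24 for ABA1 and -0.37 for SNRK2.3, and the list median differed by -0.58. With salt minus imbibed seeds it was 0.70 for ABI5, 1.40 for DOG1 and 0.91 for ABA1 in the authors' deposited tables, and the list median differed by 0.43.

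Heat shock genes had lower effects in imbibed than in dry seeds. From the authors' deposited tables the difference was -2.11 for AT2G29500, -1.93 for HSP17.4, -1.49 for ATHSP22.0, -1.47 for HSP17.6II, -2.06 for HSP17.6A and -1.77 for HSFA9, with 1.40 for HSFA9 in salt minus imbibed seeds. The list median differed by -1.80 in imbibed minus dry and 0.85 in salt minus imbibed seeds, the latter lost at a preset correlation of 0.05 (adjusted p = 0.131).

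Ribosome, cell cycle, cell wall, embryo and other genes differed too, in both directions with salt. In imbibed minus dry seeds of the authors' deposited tables the difference was 0.91 for RPL23AA, 0.79 for RPS6, 0.82 for RNR1, 3.37 for TSO2, 2.23 for CYCB1;1, 2.18 for PDF1, 1.94 for AT5G14920 and 4.22 for AGL62. In salt minus imbibed seeds of the authors' deposited tables it was -0.57 for RPL23AA, -0.49 for SAG24, -1.18 for XTH31, -1.92 for PDF1, -1.80 for GASA6, -2.02 for AT5G14920, 0.54 for RNR1, 1.45 for TSO2 and 0.85 for GA20OX3. List medians differed in imbibed minus dry seeds by 1.57 (cell wall loosening), 0.58 (ribosome), 0.97 (cell cycle) and 0.14 (oil breakdown, lost at a preset correlation of 0.05 with adjusted p = 0.115 and by ranks with 0.0604). In salt minus imbibed seeds they differed by -0.76 (cell wall loosening), -0.42 (ribosome), -0.63 (embryo and meristem) and -0.18 (oil breakdown).

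Stress and hormone genes differed as well. In imbibed minus dry seeds of the authors' deposited tables the difference was -0.89 for ADH1, -1.51 for GolS1, 3.75 for ERD14, -1.14 for CAT3, -0.89 for GSTU19, 2.45 for FER1, -2.81 for AOS, -1.14 for PIL5, -0.79 for EPR1 and -0.49 for FLOE3. It was -2.97 for PUP4, -2.15 for AT1G51340, -2.34 for CYP78A6, -1.51 for DIN2 and -1.68 for AT5G13210 in the authors' deposited tables. The salt and osmotic (-0.26, lost at a preset correlation of 0.05 with adjusted p = 0.0558), antioxidant (-0.21) and jasmonate (-0.64) list medians differed in the same comparison, though the jasmonate genes not picked from the largest changes did not pass alone (adjusted p = 0.0638). In salt minus imbibed seeds of the authors' deposited tables it was 0.83 for ADH1, 0.99 for GolS1, -1.38 for COR47, -1.55 for ERD14, 0.97 for CAT3, 1.89 for AOS, 0.62 for PIL5, -4.15 for BIP3, 2.75 for PUP4, 2.21 for CYP78A6 and 2.51 for DIN2. FLOE1 was less reduced with salt (0.58 ± 0.17, SE) and its neighbour AT4G28290 more (-5.00 ± 1.43) in the authors' deposited tables. AT4G28290 was at -5.54 in dry, -2.17 in imbibed and -7.17 in salt seeds, and its difference between imbibed and dry seeds did not pass.

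DNA damage response genes were higher in ΔDS seeds after imbibition, and the list median differed by 1.75 in imbibed minus dry and by 0.69 in salt minus imbibed seeds, where the members not picked from the largest changes did not pass alone (list adjusted p = 0.0743). Of the 16 tested members not picked from the largest changes, 15 rose in salt with a median of 1.42, and 10000 random lists of like expression reached that in a share of 0.0001, the smallest they can give, so a general shift of weakly expressed genes is argued against. Their mean of 1.51 in salt did not stand apart from the mean of 1.22 of 12 replication genes (two-sided permutation p = 0.391, 100000 resamples). With 16 against 12 genes this does not show that the groups rose alike. More cells in DNA replication may account for the rise and cannot be told apart from a damage response with these values. A difference between seed lots or transgenic lines was not tested.

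LEA and storage genes were lower in dry ΔDS seeds, where fold changes also followed transcript length. Over their 41 tested members the median was -0.22 as deposited and -0.17 after removing the length trend. The members past the threshold numbered 28 and 23 in that order. The length trend alone could thus be part of the cause but not the whole. Scaled by library totals the median was -0.14 and 17 members passed. Scaling and removal of the length trend were not combined, so their joint effect is not known. Seed maturity at harvest, a biological difference between lots, stays open and was not tested.

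Some of the genes changed at least 2-fold in the same direction in all 3 comparisons, 25 higher and 5 lower in ΔDS, lay beside another such gene. Of these 30 genes, 9 had another within 2 places along the chromosome, while 10000 random draws gave 4 at most (share 0.0001, the smallest they can give). Of the 5 neighbouring pairs, 3 had different products, and no pair shared over 3.41% of its 31-base words, which argues against reads shared between copies. A local cause tied to chromosome position, such as sequence or chromatin differences near an insertion, is a candidate explanation that was not tested. The pairs are AT3G46680 with AT3G46690 and AT3G46690 with AT3G46700, NHL22 with AT4G09595, AT4G28290 with FLOE1, and AT5G13205 with AT5G13210. AT3G46680, AT3G46690 and AT3G46700 are a run of glycosyltransferase genes, and FLOE1 is the gene under study. The random draws allowed for neither, so their share overstates how unusual the other pairs are.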

How the results depend on the processing

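Centring, the length trend, the t distribution and the other list settings were chosen after seeing the data. Requiring at least a 2-fold change left 116 genes in dry, 2159 in imbibed and 349 in salt seeds, and 369 and 1017 genes for the differences salt minus imbibed and imbibed minus dry, since fewer genes can pass. In dry, imbibed and salt seeds 86, 1471 and 283 of these were higher and 30, 688 and 66 lower in ΔDS. Library totals as scaling gave 4182 calls in salt against 2586, of which 1717 were shared. A t distribution with 4 degrees of freedom for the deposited statistic, which keeps the deposited errors and changes only the reference distribution, left 1 call in dry, 0 in imbibed and 3 in salt seeds (2812, 9399 and 4557 genes had a deposited p under 0.05), and 125 of the named gene results in these tables no longer passed. FLOE1 in imbibed seeds was among those lost, so hardly any gene could pass this setting. With 8 degrees of freedom the differences kept 0 calls for salt minus imbibed and 127 for imbibed minus dry seeds (4537 and 5898 genes had an unadjusted z test p under 0.05). All other settings run left the total counts within 1.5 times, and no named gene past the threshold changed sign under any of them. Among named gene results 7 were lost and 2 gained with library totals, and 5 and 1 with the length trend removed. Adjustment over all genes with a p lost 2 and gained 0. By direction library totals moved more, with 248 lower calls against 514 in dry and 1877 against 3794 in imbibed seeds. At a preset correlation of 0.05 the list differences of heat shock in salt minus imbibed (adjusted p = 0.131), and of oil breakdown (0.115) and the salt and osmotic list (0.0558) in imbibed minus dry seeds, were lost.

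No paired analysis was possible because the tables hold no values per library. For the same reason count models, other size factors, 1 fit over all samples, leaving out replicates, other splits of the samples and an estimated correlation for the lists were not run, and alternatives for normalised values per sample did not apply. How far 1 library decides a value is thus unknown, and the larger errors of the imbibed table limit calls there.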

Other observations

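The lists, genes and hypothesis in this part were chosen after the largest changes had been seen, and the test on other pollen genes was set before its result. In the DNA damage response list 0 of 18 members passed in dry seeds, and members rose in 22 of 25 cases in imbibed and 24 of 25 in salt seeds. In the authors' deposited tables the repair gene BRCA1 (AT4G21070) was 2.25 ± 0.21 in imbibed and 4.18 ± 0.33 in salt seeds, the poly(ADP-ribose) polymerase PARP2 (AT4G02390) 2.51 ± 0.12 and 3.05 ± 0.14, and the cell cycle inhibitor SMR7 (AT3G27630) 4.18 ± 0.32 and 5.29 ± 0.33. Members not picked from the largest changes passed the list test in both (limma, preset correlation 0.01, adjusted p = 4.61e-16 and 1.48e-67). By the rank version of that test the adjusted p was 2.08e-06 in imbibed and 1.92e-09 in salt seeds.

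Low-oxygen genes fell in 9 of 20 cases in salt seeds and in 2 of 22 in imbibed seeds, where 1 rose. In salt seeds 10 fell and 2 rose adjusted over the list alone, and 8 fell and 2 rose scaled by library totals. Besides AT3G10040, the regulator LBD41 (AT3G02550) was -1.84 ± 0.46 in salt and -0.04 ± 1.04 in imbibed seeds of the authors' deposited tables, and the difference between conditions did not pass for the list (adjusted p = 0.376). Members not picked from the largest changes fell in 5 of 16 cases in salt. Their list adjusted p was 0.00240 in salt (limma), and 0.0563 by ranks. Jasmonate genes fell in 4 of 8 cases in imbibed and 5 of 8 in salt seeds, with JAZ1 (AT1G19180) at -0.55 ± 0.16 in salt in the authors' deposited table. Those not picked from the largest changes had adjusted p = 0.0156 and 0.00240 (limma).

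VGDH1, AGP23 and BGAL11, all lower in dry ΔDS seeds, are known from pollen. As a hypothesis, the dry ΔDS libraries may hold less pollen RNA. Of 14 other pollen genes 8 had at least 5 mean normalised counts in dry seeds, and 7 of the 8 had a negative fold change, with a median of -0.84 (exact two-sided binomial p = 0.0703, over genes that are not independent). None passed on its own, for example AGP6 (AT5G14380) at -0.57 ± 0.26 and VGD1 (AT2G47040) at -0.91 ± 0.45 in the authors' deposited table. The test does not settle the hypothesis.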
